A study of Mus musculus with 10 samples.

How the data were processed

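Total RNA of isolated mouse glomeruli was sequenced in 10 libraries, and the labels put each library into 1 of 3 groups by injection and diabetes. The labels do not state whether each library came from 1 animal, and the replicate numbers used here follow the order of the records and imply no pairing. Reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.3a to the mm9 build and normalized with DESeq2 1.28.1 in R 4.0.2, per the submitters' processing notes. The deposited signal values are normalized counts, 1 table of 12934 rows by 10 libraries, which the authors made from the reads before deposit. The program that counted the reads, the annotation and the strandedness are not given in the sources used here.

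Dividing each library by the value of its single read gave whole reads for 100% of the 129340 values within a tolerance of 0.001, so the reads per library could be recovered. The table held 11869 to 12725 genes with a read per library, and no row had fewer than 7 reads in total, so genes below that are not analysed here. Of the row names, 12364 matched symbols of the GRCm38 reference table, which served for names only because the authors used another build. Of the names, 19 had the form of dates and were kept in the tests but not named. The value of 1 read was 0.62 to 1.77 normalized counts per library. Intervals and floors derived from reads cover counting error only, not variation between animals.

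Values were used as log2 of the normalized count plus 1, and folds on that scale understate the change of genes with low values. For named genes with 1 to 3 reads in each library of a group, the ratio of the summed reads per unit of depth was given with its exact conditional Poisson interval (95%). Genes with a value of at least 10 in at least 3 libraries were tested (8239 genes, with 4695 below this filter). One limma 3.58.1 fit in R 4.3.3 held all 10 libraries and the 3 groups, with an intensity trend in the moderated variance, and gave the 3 comparisons. All tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The same threshold was also applied with adjustment over the genes of each list alone. Of 32 gene lists fixed before the data were examined, the 26 with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with the correlation estimated per list, fry, and exact permutation of the libraries were run beside it. The 6 other lists (myeloid, lymphocyte, cell cycle, erythroid, liver and sex-linked genes) were summed per library and compared by exact permutation. The smallest p that exact permutation allows is 0.029 for 4 against 3 libraries (35 splits) and 0.1 for 3 against 3 (10 splits).

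Genes were named by a rule fixed before the data were examined. In the diabetes and the Esm-1 comparison it named up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold without overlap and with a mean of at least 50 in the higher group, or the 5 with the lowest p in a direction where fewer than 5 qualified. In each list it named up to 4 members past the threshold, or, where none passed, up to 2 members with the largest difference and a mean over all libraries of at least 50. Esm1, Ackr2 and Cxcl11 were named whatever their values. Members of list counts of 5 or fewer that the rule did not name were added after their values were seen. In the comparison of diabetic Esm-1 with non-diabetic saline the list part of the rule was applied to 5 lists (podocyte, endothelium, respiration, fatty acid oxidation and cholesterol synthesis), chosen after the other comparisons had been seen. Some genes that these rules select are not reported here, and they stay in every test and count.

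Alternatives fixed before the data were examined were a pseudocount of 5, no filter, a common total per library, edgeR 4.0.16 (quasi-likelihood with TMM) and DESeq2 1.42.0 on the recovered reads, limma without the intensity trend, fits of 2 groups only, a term for the title numbers under 100, leaving out the 2 libraries with such numbers, and leaving out each library in turn. Chosen after seeing the data were a term for the mean of the podocyte, endothelial and mesangial markers of each library, and a common total without Rn45s, Lars2 and Mir6236. The overlap of calls between comparisons that share libraries was compared with 100 simulations of unchanged groups, from which as many genes were taken as were called, a test added after the overlap was seen. The correlation of the diabetes and Esm-1 fold changes was compared with 100 simulations of unchanged groups and with the diabetic saline libraries divided 2 and 2 between the comparisons.

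The fits were tested on simulated data with 200 changed genes per simulation, 5 simulations per comparison. For diabetes, over 7980 genes, limma recovered 11.8%, 54.1% and 93% of the genes changed 1.5-, 2- and 4-fold, and 4.32% of its calls were false. For Esm-1 within diabetes, over 7979 genes, the shares were 10.8%, 53.7% and 94.4%, with 3.16% false. For diabetic Esm-1 against non-diabetic saline, over 7986 genes, they were 14%, 48.2% and 90.7%, with 5.84% false. No recovered gene had the wrong sign, and a list of 25 genes shifted 1.4-fold was found in 5 of 5 simulations of each comparison. Here a list counted as found at an unadjusted camera p under 0.05, and the genes were simulated independently of each other. In the data the estimated correlation reached 0.53 in the podocyte list and 0.705 in the proximal tubule list. The simulations therefore do not test camera on lists of correlated genes.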

Results

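RNA sequencing measured the transcriptome of glomeruli, the filtering units of the kidney, isolated from 17-week-old wildtype DBA/2J mice, an inbred strain that the labels describe as susceptible to diabetic kidney disease. The 10 libraries fell into 3 groups: non-diabetic saline (n = 3), diabetic saline (n = 4) and diabetic Esm-1 (n = 3). Esm-1, also called endocan, is a proteoglycan secreted by endothelial cells. At 7 weeks of age the mice received a hydrodynamic injection, a rapid high-volume injection that mainly reaches the liver, of either saline or an Esm-1 plasmid with the Sleeping Beauty transposase, an enzyme that inserts the plasmid's gene into the genome. Streptozotocin, a toxin of pancreatic beta cells, or vehicle was given from 8 weeks of age. Only the streptozotocin-treated mice were then fed a 60% high-fat diet, for 5 weeks, so the diabetes comparison is also a comparison of diets. No group received Esm-1 without diabetes. No group received a plasmid or the transposase without Esm-1 either, so the Esm-1 comparison is also one of plasmid delivery against saline.

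The non-diabetic saline libraries held 11300629, 7314053 and 5989881 reads in replicates 1 to 3. The diabetic saline libraries held 9440394, 7791986, 9370671 and 3931712 reads in replicates 1 to 4, and the diabetic Esm-1 libraries 9980593, 8238071 and 6738198 reads in replicates 1 to 3. Rn45s, the ribosomal RNA precursor, took 83.9% to 86.7% of the reads, and together with Lars2 and Mir6236 it took 91.1% to 92.8%. The reads left for every other gene numbered 338549 to 962321 per library. A count of 3 reads corresponded to 1.86 to 5.31 normalized counts depending on the library, and this floor covers counting error only. The first principal component held 32.6% of the variance and placed the non-diabetic libraries at -42.4 to -25.9, the diabetic saline libraries at 0.97 to 12.2 and the diabetic Esm-1 libraries at 11.4 to 30.8. The second held 14.3% and had non-diabetic saline replicate 3 (24.6) and diabetic saline replicate 4 (25.2) at one end, the 2 libraries with the lowest read totals and also the 2 with title numbers under 100.

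Markers of the 3 intrinsic glomerular cell types (podocytes, endothelium and mesangium, 64 tested genes) averaged highest in non-diabetic saline and lowest in diabetic Esm-1. Their mean log2 value was 6.98 ± 0.16 (SD, n = 3) in non-diabetic saline, 6.66 ± 0.24 (SD, n = 4) in diabetic saline and 6.12 ± 0.18 (SD, n = 3) in diabetic Esm-1. The difference was -0.32 ± 0.15 (SE) for diabetic against non-diabetic saline (two-sided exact permutation p = 0.17) and -0.54 ± 0.16 for diabetic Esm-1 against diabetic saline (exact permutation p = 0.057, where the smallest p the design allows is 0.029). For diabetic Esm-1 against non-diabetic saline it was -0.86 ± 0.14 (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). None of the 3 differences reached an exact permutation p under 0.05. The libraries of the saline groups overlapped, at 6.411 to 6.882 in diabetic and 6.862 to 7.165 in non-diabetic saline. The marker means stand beside every gene group described here, since their averages moved with the groups.

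The first comparison, diabetic saline (n = 4) against non-diabetic saline (n = 3), asked what diabetes with the high-fat diet changed in glomeruli. Interferon-stimulated genes, which cells switch on in response to interferons, were the group with the largest rise: 42 of the 47 tested members rose (44 adjusted over the list alone), with a median log2 difference of 1.99, or 3.96-fold. Rsad2, which encodes the antiviral enzyme viperin, rose 10.1-fold (log2 3.34, SE 0.18, adjusted p = 2e-10), from 78.9 ± 20.9 (SD) to 807.6 ± 179.5 normalized counts. Folds are on the scale of log2 of the value plus 1, which understates the change of low genes, and so differ from ratios of the mean counts given beside them. Ifit2, a binder of viral RNA, rose 10.3-fold (log2 3.36, SE 0.20) and Oas2, a sensor of double-stranded RNA, 11.1-fold (log2 3.47, SE 0.30). Usp18, a negative regulator of interferon signalling, rose 6.78-fold (log2 2.76, SE 0.25). The list was higher than the other genes by camera (adjusted p = 7.83e-74, and adjusted p = 0.016 with an estimated correlation between genes), and it was the only one of the 26 lists still past the threshold with an estimated correlation. Several of these genes belong to families of similar sequence in which this strain carries variants, so reads may be shared between members.

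**Figure D1:**
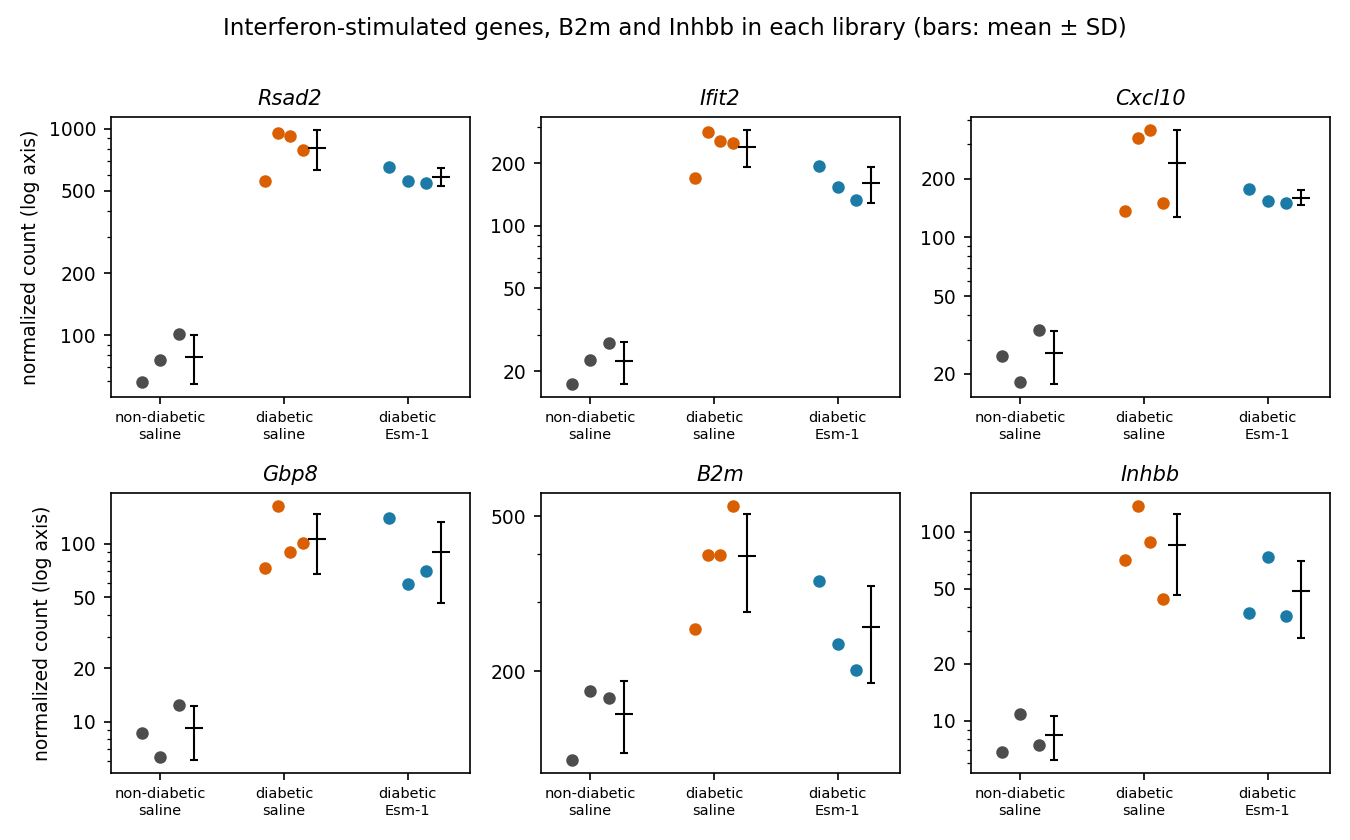
Normalized counts (log axis) of Rsad2, Ifit2, Cxcl10, Gbp8, B2m and Inhbb in each library of the 3 groups, with the mean and SD as bars. For Rsad2 the diabetic saline mean was 807.6 normalized counts against 78.9 in non-diabetic saline, and every diabetic library lay above every non-diabetic one.

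Genes of antigen presentation, chemokines and complement were also higher in diabetic saline. Of 10 antigen presentation genes 7 rose (10 adjusted over the list alone), among them H2-T23 (2.58-fold), B2m (2.49-fold, SE 0.21 on the log2 scale), the light chain of MHC class I, and H2-K1 (2.24-fold). The list had a camera adjusted p = 6.07e-12 and adjusted p = 0.0823 with an estimated correlation. Of 18 chemokine and adhesion genes 5 rose (adjusted over the list alone, 7 were higher and 2 lower). They were Cxcl10 (8.60-fold) and Cxcl11, ligands that attract activated T cells and are themselves induced by interferon, Cxcl13, a B cell attractant, Il6 (2.54-fold) and the neutrophil attractant Cxcl2 (1.75-fold), which was named after its values were seen. With 1 to 3 reads in each non-diabetic library, the summed reads per unit of depth had a ratio of 16.6 for Cxcl11 (exact 95% counting interval 7.41 to 46.3) and of 11 for Cxcl13 (5.14 to 28.2). Cxcl10 and Cxcl11 also belong to the interferon list, and camera gave adjusted p = 5.41e-05 for the chemokine list (adjusted p = 0.0888 with an estimated correlation). Complement had 1 riser among 9 genes (3 adjusted over the list alone), C4b (3.71-fold, adjusted p = 0.0181), with camera adjusted p = 0.00813 and adjusted p = 0.258 with an estimated correlation. The call of C4b ended without non-diabetic saline replicate 3 (adjusted p = 0.0688) or diabetic saline replicate 2 (adjusted p = 0.0585). That of Cxcl2 ended without non-diabetic saline replicates 1 or 2 (adjusted p = 0.0502 and 0.101) or diabetic saline replicates 1 or 3 (adjusted p = 0.0516 and 0.0507). The leukocyte markers with values, 11 of 26 listed myeloid and 2 of 23 listed lymphocyte genes, did not rise with these genes. The 13 summed to 191.3 ± 20.6 (SD, n = 4) normalized counts in diabetic and 190.9 ± 18.4 (SD, n = 3) in non-diabetic saline (two-sided exact permutation p = 1).

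Nuclear genes of mitochondrial respiration and genes of fatty acid oxidation were higher in diabetic saline. Of 48 tested subunits of the respiratory complexes 21 rose (37 adjusted over the list alone), with a median log2 difference of 0.66. Cox5b, a subunit of cytochrome c oxidase, rose 2.19-fold (log2 1.13, SE 0.17), from 73.4 to 159.7 normalized counts, and Atp5c1, a subunit of ATP synthase, 2.33-fold (log2 1.22, SE 0.24). Camera gave adjusted p = 5.27e-24, and adjusted p = 0.0888 with an estimated correlation. The number that rose was 13 without diabetic saline replicate 1. Of 24 genes of fatty acid oxidation 6 rose (10 adjusted over the list alone). One was Pdk4 (2.56-fold, SE 0.24 on the log2 scale), a kinase that restrains the use of glucose-derived pyruvate, and another Hadha (1.81-fold), which did not pass without non-diabetic saline replicate 3 (adjusted p = 0.069). Without non-diabetic saline replicate 2 the number that rose was 3. By camera this list had adjusted p = 3.03e-07 and adjusted p = 0.173 with an estimated correlation. No gene of glycolysis (16 tested, 3 higher adjusted over the list alone) or of cholesterol synthesis (15 tested, 2 higher adjusted over the list alone) passed the limma test. The glucose transporter Slc2a1 had a log2 difference of 0.55 (adjusted p = 0.0881, and 0.0476 without non-diabetic saline replicate 3) and Pkm of 0.54 (adjusted p = 0.0797). Their list medians were 0.31 and 0.53 on the log2 scale, with camera adjusted p = 0.00109 and 0.00283, and adjusted p = 0.258 and 0.303 with an estimated correlation.

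Markers of podocytes and endothelium were lower in diabetic saline. Of 25 podocyte genes 5 fell (13 adjusted over the list alone), with a median log2 difference of -0.48. They were Foxc2 (log2 -1.14, SE 0.25), Magi2 (-0.93, SE 0.21), Thsd7a (-0.84, SE 0.22), Wt1 (-0.73, SE 0.21), the podocyte transcription factor, and Synpo (-0.56, SE 0.16), an actin-binding protein of podocyte foot processes that was named after its values were seen. Of 23 endothelial genes 3 fell (5 adjusted over the list alone): Nos3, the endothelial nitric oxide synthase, by 1.92-fold (log2 -0.94, SE 0.17), from 169.3 to 87.9 normalized counts, Egfl7 (log2 -0.88) and Mmrn2 (log2 -0.59). Of 20 genes of angiogenesis, 4 of them shared with the endothelial list, Notch1 (log2 -0.88, SE 0.12) and Dll4 (log2 -1.16, SE 0.27), a receptor and its ligand in vessel sprouting, fell (3 lower adjusted over the list alone). Among 16 mesangial genes Mcam fell (log2 -0.87) and Serpine2 rose (log2 0.78), with 3 lower and 1 higher adjusted over the list alone. Camera placed all 4 lists lower, with adjusted p = 3.03e-07 for podocytes, 0.000923 for endothelium, 0.00659 for angiogenesis and 0.0213 for mesangium. With an estimated correlation the adjusted p = 0.348, 0.42, 0.296 and 0.422 in the same order. The number of podocyte genes that fell was 2 without non-diabetic saline replicate 1, 1 without replicate 2 and 2 without diabetic saline replicate 1. For endothelium it was 1 without non-diabetic saline replicates 1 or 2 or diabetic saline replicate 4, and 5 without diabetic saline replicate 2. Without non-diabetic saline replicate 1 the adjusted p was 0.0794 for Thsd7a, 0.0829 for Wt1, 0.0785 for Synpo, 0.0661 for Egfl7, 0.106 for Mmrn2, 0.0801 for Dll4 and 0.097 for Serpine2. Without replicate 2 of that group it was 0.0659 for Magi2, 0.127 for Thsd7a, 0.246 for Wt1, 0.234 for Synpo, 0.0778 for Egfl7, 0.16 for Mmrn2, 0.067 for Mcam and 0.0846 for the mesangial list. Without its replicate 3 it was 0.0615 for Foxc2, 0.0599 for Egfl7, 0.0589 for Dll4, 0.0697 for Serpine2 and 0.0619 for the mesangial list. Without diabetic saline replicate 1 it was 0.081 for Thsd7a, 0.138 for Wt1, 0.138 for Synpo, 0.105 for Mmrn2 and 0.149 for the mesangial list, and without replicate 2 it was 0.0502 for Wt1 and 0.0612 for Serpine2. Without diabetic saline replicate 3 it was 0.0883 for Thsd7a, 0.0819 for Wt1, 0.072 for Synpo, 0.0917 for Egfl7 and 0.077 for Serpine2, and without replicate 4 it was 0.0905 for Synpo, 0.0652 for Egfl7, 0.0637 for Mmrn2 and 0.0623 for the mesangial list.

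Tubular genes went both ways. Of 20 genes of the distal nephron 4 rose (7 higher and 1 lower adjusted over the list alone): Pvalb (5.15-fold), Calb1 (4.88-fold, SE 0.32 on the log2 scale), Slc12a3 (4.13-fold, SE 0.43), the thiazide-sensitive sodium chloride cotransporter, and the collecting duct water channel Aqp2 (1.86-fold, SE 0.17). Calb1 and Pvalb, which encode calcium-binding proteins, and Slc12a3 mark the distal convoluted tubule. DESeq2 did not call Slc12a3 (adjusted p = 0.0993). Of 21 genes of the proximal tubule 3 fell (3 adjusted over the list alone): Kap (log2 -2.01, SE 0.55), Slc22a6 (log2 -1.27, SE 0.37) and Cyp4b1 (log2 -1.04, SE 0.25). Camera gave adjusted p = 0.000983 for the distal list, higher, and 0.0456 for the proximal list, lower, with adjusted p = 0.42 and 0.676 with an estimated correlation. Non-diabetic saline replicate 2 decided several of these values: without it, none of the 3 proximal genes passed (adjusted p = 0.2 for Kap, 0.306 for Slc22a6 and 0.102 for Cyp4b1) and neither list did (adjusted p = 0.312 and 0.42). The proximal list turned as well, from 6 of 21 above (median -0.23) to 16 of 21 above (median 0.19). Its median was -0.72 without non-diabetic saline replicate 3, -0.50 without diabetic saline replicate 2 and -0.03 without diabetic saline replicate 3. Without diabetic saline replicate 3 none of the 3 passed either (adjusted p = 0.0928, 0.142 and 0.0523 in the same order), nor did the proximal list (adjusted p = 0.514). The proximal list also did not pass without diabetic saline replicate 1 or 4 (adjusted p = 0.066 and 0.0857), Kap without non-diabetic saline replicate 3 (adjusted p = 0.0595), and Kap and Slc22a6 without diabetic saline replicate 4 (adjusted p = 0.0887 and 0.0817).

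**Figure D2:**
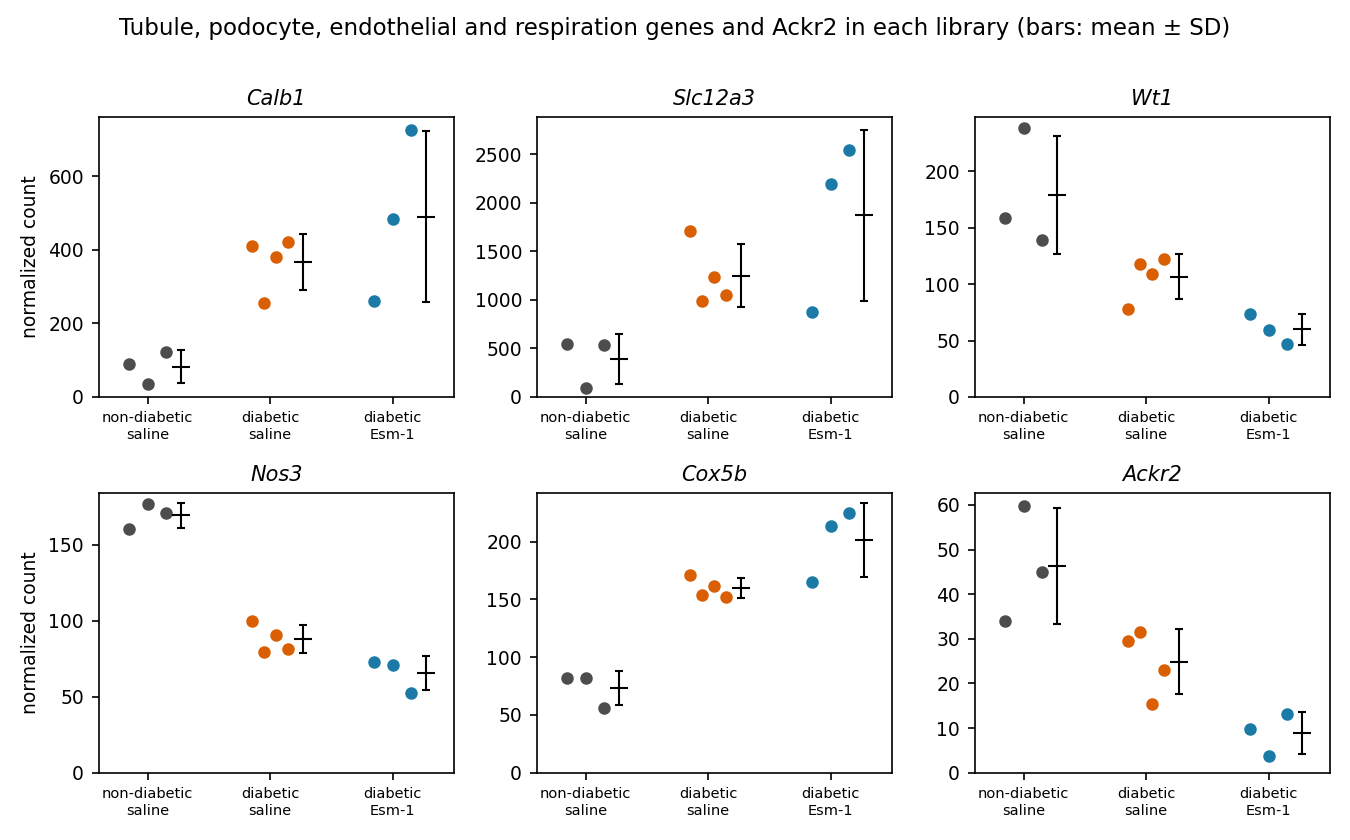
Normalized counts of Calb1 and Slc12a3 (distal tubule), Wt1 (podocytes), Nos3 (endothelium), Cox5b (mitochondrial respiration) and Ackr2 in each library of the 3 groups, with the mean and SD as bars. Nos3 averaged 169.3 normalized counts in non-diabetic saline, 87.9 in diabetic saline and 65.4 in diabetic Esm-1.

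Outside these lists, Gbp8, a guanylate-binding protein, rose 10.5-fold (log2 3.39, SE 0.29) and Inhbb, the beta B subunit of inhibins and activins, 8.64-fold on the log2 scale of the value plus 1 (log2 3.11, SE 0.31), with mean normalized counts of 8.39 and 85.3. Ifi202b, an interferon-inducible gene, rose by 2.70 on the log2 scale (SE 0.32). Among called genes without overlap between the groups and with a mean of at least 50 normalized counts in the higher one, the largest falls were in Cyp2d22, a cytochrome P450 (3.20-fold lower, from 72.7 to 22.2 normalized counts), Dock4 (2.45-fold lower), Ltbp4, a binding protein of latent TGF-beta (2.37-fold lower), and Speg (2.33-fold lower). In the matrix list, 1 of 26 genes rose and 1 fell (1 higher and 2 lower adjusted over the list alone, the second being Col15a1): Ctgf, a matrix-associated growth factor, fell (log2 -0.90, SE 0.19). The matrix list did not pass camera (adjusted p = 0.53). No gene of the glycocalyx and proteoglycan list, the family to which Esm-1 belongs, passed limma among 23 tested (0 adjusted over the list alone), with Chst15 at log2 0.49 (adjusted p = 0.185) and Agrn at 0.49 (adjusted p = 0.0855, and 0.0226 without diabetic saline replicate 4). The test of this list gave adjusted p = 0.996.

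Among the remaining lists, Sox4 was the 1 riser of 16 kidney injury genes (1.82-fold, 1 higher adjusted over the list alone), and this list was higher by camera (adjusted p = 0.0217, and 0.45 as adjusted p with an estimated correlation). The injury list did not pass without non-diabetic saline replicate 2 (adjusted p = 0.646) or diabetic saline replicates 1, 3 or 4 (adjusted p = 0.066, 0.0505 and 0.0517). The unfolded protein response list was lower (adjusted p = 0.00826, and adjusted p = 0.319 with an estimated correlation) with 1 faller of 20, Trib3 (log2 -1.30, 2 lower adjusted over the list alone), which did not pass without non-diabetic saline replicate 1 or 3 (adjusted p = 0.0542 and 0.0881). Nr1d1, a repressor of the circadian clock, was the 1 faller of 16 clock genes (log2 -0.75, 1 adjusted over the list alone, camera adjusted p = 0.543). The lists of smooth muscle and renin cells (7 genes, adjusted p = 0.223), glucose handling (16 genes, adjusted p = 0.91), immediate-early genes (24 genes, adjusted p = 0.07) and ribosomal proteins (42 genes, adjusted p = 0.0624) did not pass camera, and none of their genes passed limma or the adjustment over the list alone. Leaving out 1 library brought 3 of them past: immediate-early genes without non-diabetic saline replicate 2 or diabetic saline replicates 3 or 4 (adjusted p = 0.0149, 0.00875 and 0.0245), ribosomal proteins without non-diabetic saline replicate 1 or diabetic saline replicates 1 or 4 (adjusted p = 0.0243, 0.0439 and 0.0418), and smooth muscle and renin cells without non-diabetic saline replicate 2 (adjusted p = 0.0468). In the glycocalyx, glucose handling and clock lists the median, the mean and the direction of the test did not all have the same sign.

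Parietal epithelium, oxidative stress and hypoxia did not pass camera either (adjusted p = 0.188, 0.53 and 0.623), though some of their genes did singly. Of 10 parietal genes 3 rose (3 adjusted over the list alone): Aldh1a2 (log2 1.62, SE 0.42), an enzyme of retinoic acid synthesis, Wfdc2 (1.08, SE 0.29) and Krt7 (0.60, SE 0.17), an epithelial keratin. Of 20 oxidative stress genes Mt1, a metallothionein, rose (log2 0.91, SE 0.24), with 2 higher and 1 lower adjusted over the list alone. Of 13 hypoxia genes P4ha2 (log2 -0.96, SE 0.27) and Adm, the vasodilator adrenomedullin (log2 -0.84, SE 0.23), fell, with 2 higher and 2 lower adjusted over the list alone. Every one of these calls ended on leaving out single libraries. Without non-diabetic saline replicate 1 the adjusted p was 0.0544 for Krt7, 0.0674 for Mt1, 0.118 for P4ha2 and 0.0521 for Adm. Leaving out replicate 2 of that group gave 0.0613 for Aldh1a2, 0.195 for Wfdc2, 0.23 for Krt7, 0.122 for Mt1, 0.155 for P4ha2 and 0.174 for Adm, and leaving out replicate 3 gave 0.0884 for Aldh1a2, 0.0615 for P4ha2 and 0.057 for Adm. Without diabetic saline replicate 1 it was 0.082 for Wfdc2, 0.0603 for Krt7, 0.0681 for P4ha2 and 0.0552 for Adm, and without replicate 2 it was 0.101 for Aldh1a2. Leaving out diabetic saline replicate 3 gave 0.0822 for Aldh1a2, 0.0816 for Wfdc2, 0.106 for Krt7, 0.0709 for Mt1, 0.0724 for P4ha2 and 0.0694 for Adm, and leaving out replicate 4 gave 0.0686 for Wfdc2, 0.0641 for Krt7, 0.0686 for Mt1, 0.0637 for P4ha2 and 0.0922 for Adm.

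Some genes passed only when adjusted over their list alone, and were named after their values were seen. Lower were Pecam1 (log2 -0.50, adjusted p = 0.0698) and Flt1 (-0.50, 0.0644) of the endothelial list, the latter also of the angiogenesis list, Des (-0.79, 0.0672) and Gucy1a3 (-0.87, 0.0932) of the mesangial list, and Umod (-0.76, 0.152) of the distal nephron. The decoy receptor Ackr3 (-1.06, 0.0797), Col15a1 (-1.02, 0.072), Hmox1 (-0.83, 0.0532) and Sesn2 (-0.73, 0.0584) were lower as well. Higher were Serping1 (log2 0.78, adjusted p = 0.132) and C1ra (0.94, 0.0752) of the complement list, Aldoa (0.43, 0.0644) of glycolysis, Hmgcs1 (1.58, 0.0607, with 1 to 3 reads in each non-diabetic library and a ratio of summed reads per unit of depth of 3.84, exact 95% counting interval 1.66 to 10.3) and Msmo1 (1.05, 0.0663) of cholesterol synthesis, Sod2 (0.52, 0.065) and Pdk1 (1.14, 0.0507). Without diabetic saline replicate 2, Pecam1 (adjusted p = 0.0414), Flt1 (0.0455), Des (0.0348), Col15a1 (0.0432), Aldoa (0.0478) and Msmo1 (0.0178) passed over all genes. Without non-diabetic saline replicate 2, Umod (adjusted p = 0.014), Hmox1 (0.0012) and Sesn2 (0.0171) did, without its replicate 1 Pdk1 (0.0355), without diabetic saline replicate 1 Umod (0.027), and without replicate 4 Hmox1 (0.0195) and C1ra (0.0449).

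Gene sets with too few tested members for camera were summed. In non-diabetic saline, diabetic saline and diabetic Esm-1 the 11 myeloid genes summed to 175.4, 184.3 and 152.4 normalized counts, 2 lymphocyte genes to 15.4, 6.98 and 6.77, and 15 cell cycle genes to 116.9, 130.3 and 104.3. The 4 erythroid genes summed to 76.8, 61.6 and 42.6, 5 liver genes to 71.6, 102.9 and 134.6, and 4 sex-linked genes to 93.7, 104.8 and 104.6. The lowest exact permutation p among these was 0.057, for lymphocyte genes between the saline groups and for erythroid genes between the diabetic groups.

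In all, 456 of 8239 tested genes differed between diabetic and non-diabetic saline in the limma test, 307 higher and 149 lower, and 240 of them by at least 2-fold. Of the 456, 430 had no overlap between the groups. Over all tested genes 1362 (16.5%) had none, where chance gives 5.71%. edgeR called 517 genes and DESeq2 409. The count was 296 without non-diabetic saline replicate 1, 289 without its replicate 2 and 292 without diabetic saline replicate 3. It was 252 with the mean of the glomerular markers as a term in the fit, a setting chosen after seeing the data, and 224 without the intensity trend. With the glomerular term 43 interferon genes, 7 respiration genes and 0 fatty acid oxidation genes rose. The respiration list (48 of 48 above, median 0.58) and the fatty acid list (22 of 24 above, median 0.50) still passed camera with the term (adjusted p = 8.49e-16 and 3.87e-05). Under it the lists of angiogenesis, distal nephron, proximal tubule and kidney injury did not pass camera (adjusted p = 0.459, 0.511, 0.679 and 0.711), the proximal list with its direction turned to higher. Without the trend 7 respiration, 2 fatty acid oxidation and 3 antigen presentation genes rose, and 1 podocyte, 1 endothelial and 0 proximal tubule genes fell.

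The second comparison, diabetic Esm-1 (n = 3) against diabetic saline (n = 4), asked what the Esm-1 plasmid with its transposase changed in diabetic glomeruli. No gene passed the limma test among 8239, against 899 at an unadjusted p under 0.05, 0 called by edgeR and 30 by DESeq2. The values of whole groups leaned one way: all 25 podocyte genes, all 23 endothelial genes and all 16 mesangial genes lay below their diabetic saline level, with median log2 differences of -0.68, -0.44 and -0.54. Wt1 averaged 59.8 ± 13.5 (SD, n = 3) against 106.7 ± 20.1 (SD, n = 4) normalized counts (log2 -0.83, SE 0.21, adjusted p = 0.145), the endothelial co-receptor Eng 171.1 against 294.9 (log2 -0.75, adjusted p = 0.136) and the mesangial filament gene Des 22.9 against 50.3 (log2 -1.09, adjusted p = 0.136). Adjusted over the list alone, 19 podocyte, 11 endothelial and 7 mesangial genes were lower. Camera gave adjusted p = 2.83e-20, 8.77e-12 and 3.03e-08 for the 3 lists, and adjusted p = 0.187 for each with an estimated correlation. Exact permutation of the list means gave unadjusted p = 0.086 for podocytes and 0.057 for each of the others. The podocyte mean of diabetic saline replicate 1 (7.22) lay below that of diabetic Esm-1 replicate 1 (7.26).

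Interferon-stimulated genes lay below diabetic saline in 47 of 47 cases, by a median log2 difference of -0.34, or 1.27-fold lower. After scaling to a common total without the 3 ribosomal-type rows, a setting chosen after seeing the data, 46 of 47 lay below. None passed singly or adjusted over the list alone, and 13 had an unadjusted p under 0.05 with a lower value. Igtp had a log2 difference of -0.61 (adjusted p = 0.367) and Iigp1 of -0.58 (adjusted p = 0.37), both interferon-inducible GTPases. Camera gave adjusted p = 1.64e-09 and adjusted p = 0.253 with an estimated correlation. The mean of the glomerular markers, -0.54 lower on the log2 scale, moved with this group. With that mean as a term, also chosen after seeing the data, 28 lay above and 19 below diabetic saline (median 0.07), Igtp and Iigp1 had differences of 0.25 and 0.26, and the list no longer passed camera (adjusted p = 0.767). That mean was 5.93 to 6.28 in the diabetic Esm-1 libraries and 6.41 to 6.88 in diabetic saline, without overlap. The term thus follows the groups of this comparison, and values with it do not separate a lower glomerular share from the Esm-1 plasmid injection. The interferon list stayed well above non-diabetic saline: its median in diabetic Esm-1 was 3.37-fold the non-diabetic level. Antigen presentation genes (10 tested, camera adjusted p = 0.454, B2m log2 -0.60 with adjusted p = 0.278) and complement genes (9 tested, camera adjusted p = 0.697) did not pass. C3, named after its values were seen, was the 1 complement gene higher adjusted over the list alone (log2 0.96, SE 0.25, adjusted p = 0.163 over all genes).

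**Figure D3:**
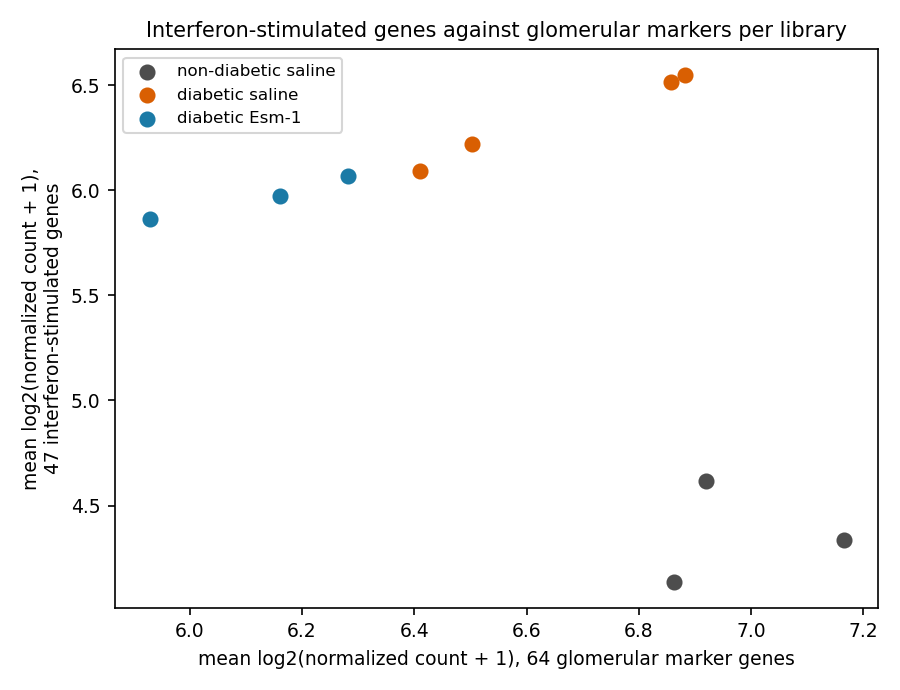
Mean log2 value of the 47 interferon-stimulated genes against the mean log2 value of the 64 glomerular marker genes, 1 point per library, by group. The glomerular mean of the diabetic Esm-1 libraries (group mean 6.12) lay below that of the diabetic saline libraries (group mean 6.66).

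Proximal tubule genes lay above diabetic saline in 20 of 21 cases (median log2 difference 0.63, and 0.40 without diabetic Esm-1 replicate 1), and none passed singly or adjusted over the list alone. Cubn, an endocytic receptor of the proximal tubule, had a log2 difference of 1.04 (SE 0.44, adjusted p = 0.373) and the fatty acid transporter Slc27a2 of 0.86 (adjusted p = 0.367). For this list camera gave adjusted p = 3.58e-07, and adjusted p = 0.376 with an estimated correlation. With the mean of the glomerular markers as a term, a setting chosen after seeing the data, 21 of 21 lay above (median 1.35). Under the same setting the distal nephron genes turned, from 15 of 20 above (median 0.19) to 17 of 20 below (median -0.43). Without the term their median was 0.32 without diabetic Esm-1 replicate 1, 0.08 without its replicate 3 and 0.12 without diabetic saline replicate 2. Genes of mitochondrial respiration (45 of 48 above, median 0.25), cholesterol synthesis (15 of 15 above, median 0.45) and fatty acid oxidation (20 of 24 above, median 0.22) were higher by camera as well, with adjusted p = 3.46e-08, 1.8e-05 and 0.00878. With an estimated correlation they had adjusted p = 0.255, 0.187 and 0.406. With the glomerular term the respiration and fatty acid lists no longer passed (adjusted p = 0.398 and 0.767, with 29 of 48 and 15 of 24 above), and the cholesterol list had adjusted p = 0.0447. None of the respiration or fatty acid oxidation genes passed singly or adjusted over the list alone. Without diabetic Esm-1 replicate 1 the medians were 0.39, 0.72 and 0.39 in the same order. The fatty acid list did not pass without diabetic Esm-1 replicate 2 (median 0.11, adjusted p = 0.359).

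Extracellular matrix genes were lower by camera (median -0.39, 8 of 26 lower adjusted over the list alone, adjusted p = 8.41e-06), as were angiogenesis (median -0.31, 0 of 20, adjusted p = 0.0009), immediate-early (median -0.21, 0 of 24, adjusted p = 0.000528) and glycocalyx genes (median -0.19, 3 of 23, adjusted p = 0.0266). The 3 were Chst15, Bgn and Sulf1, the last 2 named after their values were seen. With an estimated correlation these had adjusted p = 0.187, 0.223, 0.253 and 0.303. The glomerular term, chosen after seeing the data, ended the calls of matrix, angiogenesis and glycocalyx (adjusted p = 0.98, 0.951 and 0.976), with the direction of matrix and angiogenesis turned to higher, and left immediate-early genes at 0.016. Sparc had a log2 difference of -0.69 (adjusted p = 0.225, and 0.38 as the difference with the glomerular term) and Chst15, a chondroitin sulfotransferase, of -0.64 (adjusted p = 0.23). The glycocalyx list did not pass without diabetic saline replicate 3 (adjusted p = 0.134) or diabetic Esm-1 replicate 1 (adjusted p = 0.15). In the smooth muscle and renin list Mylk (log2 -0.72, adjusted p = 0.14) and Myl9 (-0.86, 0.219, named after its values were seen) were lower adjusted over the list alone. The lists that did not pass camera were smooth muscle and renin cells (adjusted p = 0.509), distal nephron (0.0989), parietal epithelium (0.975), kidney injury (0.168), chemokines and adhesion (0.364), glycolysis (0.212), glucose handling (0.0746), oxidative stress (0.117), unfolded protein response (0.432), hypoxia (0.471), clock (0.961) and ribosomal proteins (0.411). In the glucose handling list Khk, which phosphorylates fructose and was named after its values were seen, was the 1 gene higher adjusted over the list alone (log2 0.86, adjusted p = 0.152 over all genes). Leaving out 1 library brought some of these past: distal nephron without diabetic saline replicate 3 or diabetic Esm-1 replicate 1 (adjusted p = 0.0314 and 0.0498), glucose handling without diabetic saline replicate 2 (adjusted p = 0.00495), and glycolysis and oxidative stress without diabetic Esm-1 replicate 1 (adjusted p = 0.0498 for both). The glomerular term brought 2 past, distal nephron, lower (adjusted p = 0.000488), and glucose handling, higher (adjusted p = 0.00561). The median, mean and test direction did not share a sign in the smooth muscle, parietal and clock lists. In all 12 lists passed camera, 4 higher and 8 lower, none passed with an estimated correlation, and fry, a rotation test of each list by itself, placed 0 past the threshold. Exact permutation of the list means, adjusted over the lists, also placed 0 past it (lowest adjusted p = 0.27).

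**Figure D4:**
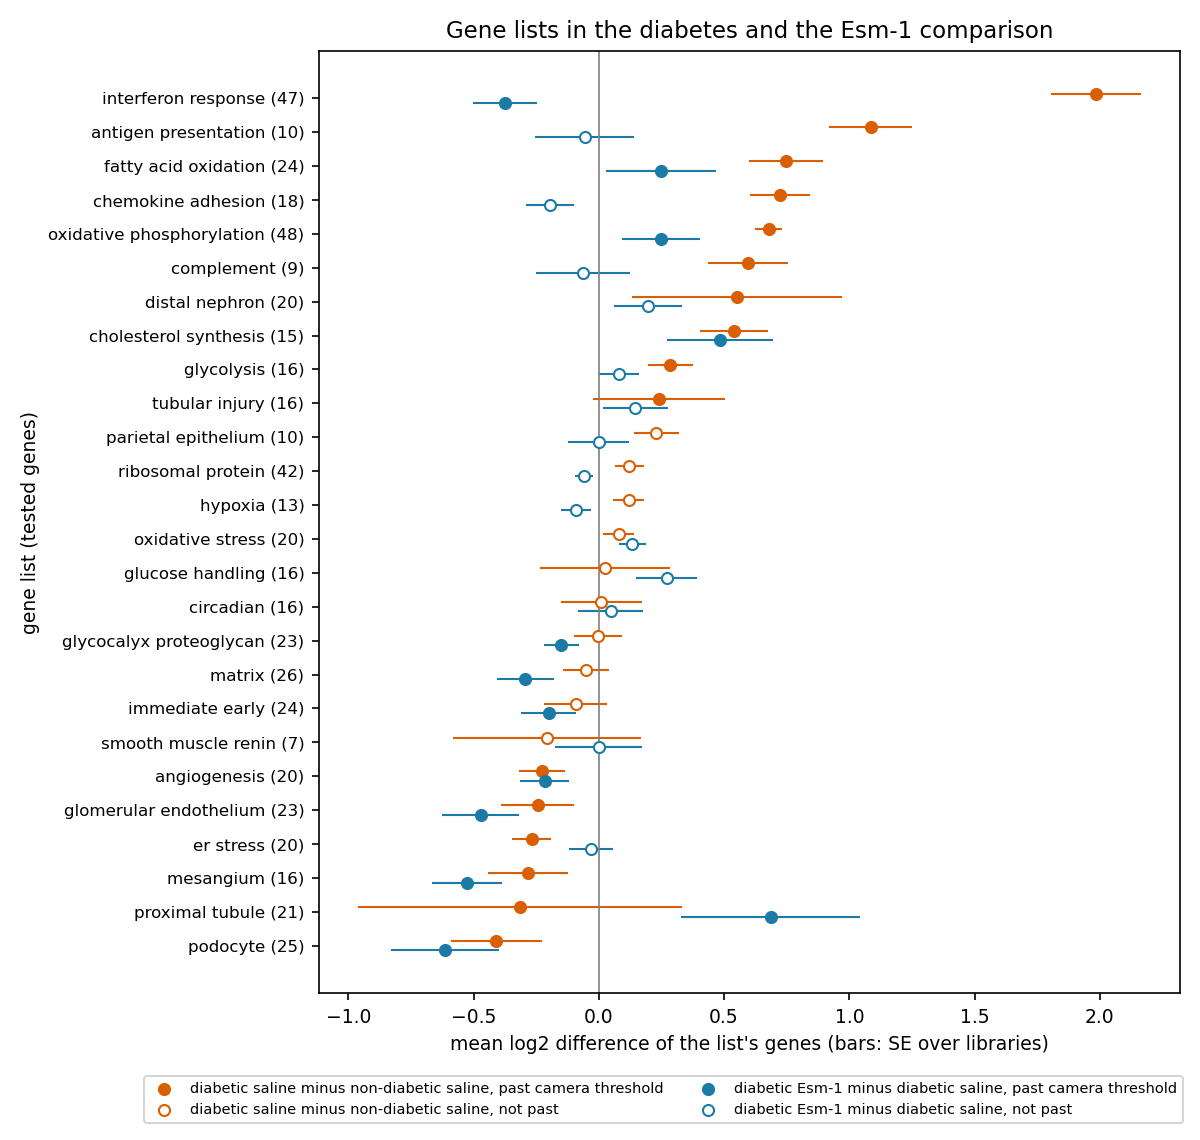
Mean log2 difference of each gene list, with its SE over libraries as bars, for diabetic saline minus non-diabetic saline and for diabetic Esm-1 minus diabetic saline, filled where camera passed its threshold. The interferon list had a median log2 difference of 1.99 in the first comparison and of -0.34 in the second.

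The genes with the lowest p that were higher in diabetic Esm-1 were Echs1, an enzyme of fatty acid oxidation (log2 1.08, adjusted p = 0.136), Usp24 (0.65, adjusted p = 0.136), Osbpl3 (0.98, adjusted p = 0.136), Tec (1.35, adjusted p = 0.149) and Plekha7 (1.06, adjusted p = 0.149). Those lower were the glucose transporter Slc2a3 (log2 -2.17, adjusted p = 0.126, with 3 reads in each Esm-1 library and a ratio of summed reads per unit of depth of 0.169, exact 95% counting interval 0.0741 to 0.343), the prostaglandin transporter Slco2a1 (-0.74, adjusted p = 0.136), Daam2 (-1.04), C1qtnf1 (-0.86) and Slc9a3r2 (-0.93). Of the 899 genes at an unadjusted p under 0.05, 309 were higher and 590 lower. The lowest adjusted p in limma was 0.126. Of the 30 genes DESeq2 called, 29 were lower and 1, Usp24, was higher, among 1690 genes to which it gave an adjusted p. Eng, Slco2a1, Daam2 and C1qtnf1 each had adjusted p = 0.0166 in DESeq2. Leaving out diabetic saline replicate 1, limma called 52 genes (7 higher and 45 lower), among them Wt1, Eng and Des (adjusted p = 0.0459, 0.0275 and 0.0282), and without diabetic Esm-1 replicate 1 it called 10, all lower, with Mylk among them (adjusted p = 0.048). Over all tested genes, 758 (9.2%) had no overlap between the groups, where chance gives 5.71%.

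Esm1 itself was barely detected in glomeruli, with 6 reads in the 3 non-diabetic saline libraries, 8 in the 4 diabetic saline libraries and 14 in the 3 diabetic Esm-1 libraries. The Esm-1 libraries had 6.51, 3.81 and 0 normalized counts in replicates 1 to 3. In a fit without the filter on low values the log2 difference from diabetic saline was 0.24 (SE 0.66, adjusted p = 0.948). It was -0.35, -0.03 and 1.11 without diabetic Esm-1 replicates 1, 2 and 3, and 0.44 and 0.06 without diabetic saline replicates 1 and 2. Ackr2, a receptor that scavenges inflammatory chemokines, averaged 46.3 ± 13.0 (SD, n = 3), 24.9 ± 7.24 (SD, n = 4) and 8.92 ± 4.74 (SD, n = 3) normalized counts in non-diabetic saline, diabetic saline and diabetic Esm-1. Its log2 difference was -0.88 (SE 0.34, adjusted p = 0.149) for diabetes and -1.47 (SE 0.34, adjusted p = 0.136) for Esm-1 within diabetes, and in both it was lower adjusted over the chemokine list alone. All 3 Esm-1 libraries (3.81 to 13.2 normalized counts) lay below all 4 diabetic saline libraries (15.5 to 31.5). Cxcl11 averaged 2.06 ± 1.57, 26.4 ± 17.2 and 12.3 ± 2.89 normalized counts in the same order, and its log2 difference for Esm-1 within diabetes was -0.80 (SE 0.50, adjusted p = 0.604), and 0.74 with the glomerular term.

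The last comparison, diabetic Esm-1 (n = 3) against non-diabetic saline (n = 3), joined both treatments. Most glomerular markers fell: 20 of 25 podocyte genes (21 adjusted over the list alone), 16 of 23 endothelial genes (16) and 8 of 16 mesangial genes (9). Wt1 fell by 2.93-fold (log2 -1.55, SE 0.22, adjusted p = 0.000124), from 179.1 ± 52.4 (SD) to 59.8 ± 13.5 normalized counts, and Thsd7a by 2.98-fold (log2 -1.58, SE 0.24). Nos3 was 2.59-fold lower (log2 -1.37, SE 0.18) and Mmrn2 2.35-fold lower (log2 -1.23, SE 0.17). Interferon-stimulated genes rose in 39 of 47 cases (43 adjusted over the list alone), with a median log2 difference of 1.75. Genes of mitochondrial respiration rose in 39 of 48 cases (45 adjusted over the list alone), with Cox5b 2.73-fold higher (log2 1.45, SE 0.18), from 73.4 to 201.1 normalized counts, and Ndufs8 2.57-fold higher.

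Genes of fatty acid oxidation rose in 12 of 24 cases (14 adjusted over the list alone), Eci1 by 3.22-fold (log2 1.69, SE 0.36). Genes of cholesterol synthesis rose in 7 of 15 cases (9 adjusted over the list alone). Matrix genes fell in 8 of 26 cases (8) and angiogenesis genes in 8 of 20 (10). Ackr2 fell by 5.11-fold (log2 -2.35, SE 0.36, adjusted p = 0.000214, and 0.165 with the glomerular term) and Cxcl11 rose (ratio of summed reads per unit of depth 7.55, exact 95% counting interval 3.20 to 21.7, adjusted p = 0.00715). Camera placed 16 of 26 lists past the threshold, 9 higher and 7 lower, and none passed with an estimated correlation (lowest adjusted p = 0.108, for podocytes and interferon-stimulated genes among others). The number of endothelial genes that fell was 9 without diabetic Esm-1 replicate 3, and the number of respiration genes that rose was 24. For fatty acid oxidation it was 6 without diabetic Esm-1 replicate 2 and 7 without replicate 3, and for cholesterol synthesis 3 and 2.

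Markers of the distal nephron moved the other way from the glomerular ones. Genes of the distal nephron rose in 8 of 20 cases (9 adjusted over the list alone, median log2 difference 0.57), Calb1 by 2.61 on the log2 scale (SE 0.34) and Slc12a3 by 2.52 (SE 0.46). Calb1 and Slc12a3 had been named for the diabetes comparison and were not selected by the rule in this one. Kidney injury genes lay above non-diabetic saline in 13 of 16 cases (median 0.57). Camera gave adjusted p = 0.000226 and 0.00645 for the 2 lists, higher, and adjusted p = 0.319 and 0.336 with an estimated correlation. Proximal tubule genes did not pass (adjusted p = 0.168, and 2.21e-05, higher, without non-diabetic saline replicate 2). Without that replicate the distal nephron had 4 risers (median 0.25) and the injury list did not pass (median 0.23, adjusted p = 0.121). Distal risers also numbered 4 without diabetic Esm-1 replicate 2 or 3. With the glomerular term neither list passed (adjusted p = 0.189 and 0.428), both directions turned to lower, and 0 distal genes rose and 2 fell. The proximal list passed with it, higher (adjusted p = 3.17e-08), and the matrix and angiogenesis lists did not (adjusted p = 0.546 and 0.869).

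In all, 1260 genes differed in limma, 592 higher and 668 lower, 624 of them by at least 2-fold, and edgeR called 1294 and DESeq2 1039. Of the tested genes, 2703 (32.8%) had no overlap between the groups, where chance gives 10%. The count was 704 without diabetic Esm-1 replicate 2 and 626 without replicate 3. It was 59 with the mean of the glomerular markers as a term and 791 without the intensity trend. That mean was 5.929 to 6.282 in diabetic Esm-1 and 6.862 to 7.165 in non-diabetic saline, without overlap. The term thus follows the groups here too. With the glomerular term 24 of the 47 interferon genes and 0 of the 48 respiration genes rose, while both lists still passed camera, higher (adjusted p = 6.53e-56 and 3.31e-09, medians 2.21 and 0.61).

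The genes called in the first and last comparisons overlapped: 261 were higher in both and 124 lower in both, where independent lists would share 22.1 and 12.1, and 0 went opposite ways. Unchanged groups, simulated 100 times, had 0.04 and 0.02 called genes on average, too few to share any. With as many genes taken from the top of each simulated ranking as were called here, 125 (102 to 142) were shared among the higher and 77.2 (68 to 89) among the lower. Neither value holds both the effects and the shared libraries, so the excess over them is not a measure of a shared effect. Both comparisons use the same 3 non-diabetic libraries, which are too few to divide between them, so part of the overlap can come from sharing them. Across the 8239 genes, the fold changes for diabetes and for Esm-1 within diabetes had a Pearson correlation of -0.02, a correlation across genes, which are not independent replicates. Groups simulated without change gave -0.43 on average (-0.46 to -0.38 over 100 simulations), because both fold changes use the diabetic saline libraries. With those libraries divided between the comparisons the correlation was 0.17 on average (0.09 to 0.24 over 6 ways to divide them). On leaving out 1 library the correlation ranged from -0.16, without diabetic saline replicate 1, to 0.05, without diabetic Esm-1 replicate 1.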

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

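Of the tests in this part, those of the glomerular share behind the lower interferon values, of podocyte loss and of tubular RNA were chosen only after the result was seen, as was the glomerular marker term used for the interferon rise. In the group of 4 diabetic saline libraries, 183 values were checked for a library far from the other 3, and 7 were found. Chance gives about 1 in 20, so the 7 are no more than chance alone would give. By the size of the gap relative to the range, replicate 1 lay apart in Mylk (0.845, 207.2 against 280.8 to 294.3 normalized counts), Ifi27l2a (0.873, 19.2 against 37.2 to 39.8), Daam2 (0.88, 76.8 against 113.8 to 118.9), C1qtnf1 (0.911, 132 against 210.1 to 217.8) and the sum of the cell cycle genes (0.83, 96.8 against 136.3 to 144.4). Replicate 4 lay apart in Hspa1a (0.873, 950.7 against 120 to 225.7), a heat shock gene. Replicate 3 lay apart in the mean of the ribosomal protein genes (0.877, 6.45 against 6.30 to 6.32 on the log2 scale).

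The first pattern weighed was the rise of interferon-stimulated genes in diabetic saline. The summed leukocyte markers differed by 0.0011 on the log2 scale (SE 0.11), where the list median rose by 1.99. Only 11 of 26 listed myeloid and 2 of 23 listed lymphocyte genes had values, and 3 myeloid and 0 lymphocyte genes passed the filter on low values. The summed markers did not rise with the interferon list, so they give no sign of more myeloid RNA. With so few markers measured they do not exclude it, and 2 genes are too few to judge lymphocyte RNA. A lower glomerular share of the RNA does not explain the rise, since 42 of 42 called members stayed past the threshold with the glomerular marker term (median 2.07). Diabetes and its diet, which the design does not separate, stay among the open explanations and were not tested.

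The second pattern was the lower level of these genes in diabetic Esm-1. The interferon mean minus the glomerular marker mean was higher in diabetic Esm-1 by 0.165 (SE 0.05, two-sided exact permutation p = 0.029, the smallest possible), so the interferon genes fell less than the glomerular markers did. This goes with a lower glomerular share of the RNA. A lower interferon response to Esm-1 or to its plasmid was not separated from that share. The leukocyte markers changed by -0.27 (SE 0.14), which leaves a loss of leukocyte RNA undecided.

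The third pattern was the lower level of podocyte, endothelial and mesangial markers in diabetic Esm-1. Loss of podocytes alone would leave the endothelial and mesangial means level. The smaller of their falls was -0.47 on the log2 scale (two-sided exact permutation p = 0.057 for each list). These falls are part of the pattern as it was defined, so the test repeats the pattern and is no separate evidence. More tubular RNA in the diabetic Esm-1 preparations and an effect of Esm-1 or its plasmid on glomerular cells cannot be told apart here. The proximal tubule mean was higher by 0.69 (SE 0.36) and the distal nephron mean by 0.20 (SE 0.14).

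Other splits of the same libraries were tried for each count. For genes changed in diabetes, 1 of 35 splits, the real one, gave a count as large (456, highest other 44). That share, 0.029, is the smallest the design allows, so the count stands apart from the other splits but chance is not excluded. For the diabetes lists 1 of 35 gave as many (16, highest other 15). The margin was 1 list only, and leaving out 1 library gave 14 to 17 lists. The number of lists is therefore not set clearly apart from chance. For genes in Esm-1 within diabetes, 35 of 35 splits gave as many as the real 0, with 68 as the highest of the others. A real count of 0 fixes that outcome, so these splits decide nothing about chance. The split with 68 differed from the real one only in placing diabetic saline replicate 1 with the Esm-1 libraries, and leaving out that replicate gave 52 genes. It points to a structure of the samples whose cause was not tested. That replicate had the lowest glomerular marker mean of diabetic saline (6.411, against 5.929 to 6.282 in diabetic Esm-1). Its podocyte mean (7.223) lay below that of diabetic Esm-1 replicate 1 (7.259). Placing diabetic saline replicate 4, the next lowest in glomerular mean, with the Esm-1 libraries instead gave 0 genes. The values rest on single libraries and do not settle what sets replicate 1 apart. For the lists of that comparison 2 of 35 splits gave as many (12, highest other 13), so chance cannot be excluded. For diabetic Esm-1 against non-diabetic saline the 10 splits are too few (1260 genes in 1 split, the real one, highest other 0).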

How the results depend on the processing

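The added settings, the glomerular marker term and the total without 3 rows of ribosomal type, were chosen only after the results were seen. Reads outside those rows numbered 338549 to 962321 per library, and in simulations with this depth and number of libraries limma recovered 11.8% of genes changed 1.5-fold by diabetes. The cause was not tested for any of the values that follow.

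Without the intensity trend the count of genes was 224 for diabetes and 791 for diabetic Esm-1 against non-diabetic saline. With the glomerular term it was 252 and 59, and DESeq2 called 30 genes for Esm-1 within diabetes. Leaving out 1 library gave 289 to 453, 626 to 1227 and 0 to 52 genes in the same order. For the lists, an estimated correlation left 1 in diabetes and 0 in Esm-1 within diabetes, fry 7 and 0, and the glomerular term 9 and 5, and leaving out 1 library gave 14 to 17 and 11 to 14. Exact permutation of the list means gave an unadjusted p under 0.05 for 9 and 0 lists in the same order. Adjusted over the lists it left 0 in both, with lowest adjusted p = 0.083 and 0.27. The correlation of fold changes was 0.17 with split libraries and -0.20 without a filter, and -0.16 to 0.053 on leaving out 1 library. The log2 difference of Esm1 itself ranged from -0.35 to 1.11 on leaving out 1 library.

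The glomerular marker mean of diabetic Esm-1 did not overlap with that of either saline group, so its term follows the groups of both Esm-1 comparisons. With the glomerular term these log2 differences turned in sign. For diabetes it became 0.18 for Slc5a2. For Esm-1 within diabetes they became 0.10 for Nt5e, -1.14 for Slc12a1, -0.42 for Umod, -0.34 for Wfdc2, -0.35 for Spp1, -0.072 for Vcam1, 0.25 for Igtp, 0.26 for Iigp1, 0.34 for H2-T23, 0.36 for Cxcl10, 0.38 for Sparc, 0.14 for Loxl2, 0.037 for Sdc3, 0.11 for Efnb2, -0.34 for Pfkp, -0.13 for Pkm, -0.0064 for Srebf2, -0.23 for Sesn2, 0.014 for Adm and 0.74 for Cxcl11. For diabetic Esm-1 against non-diabetic saline it became 0.41 for Icam2. Hspa1a became 0.047 without the title numbers under 100 in Esm-1 within diabetes.

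On leaving out 1 library, the genes that turned had ranges of -0.86 to 0.24 for Slc5a2 in diabetes, and of -0.039 to 0.49 for Cfb and -0.94 to 0.047 for Hspa1a in Esm-1 within diabetes. Of 95 genes named for diabetes, 1451 of 1709 values kept direction and side of the threshold, 206 lost the threshold and 50 gained it. Among those 95 genes 66 were called, and 31 of the 66 lost the call on leaving out some single library. For 65 genes in Esm-1 within diabetes, of which 0 were called, 1102 of 1146 kept both and 21 gained the threshold. For 21 genes in the last comparison, all called, 309 of 355 kept both and 45 lost it, and 6 of the 21 lost the call on leaving out some single library.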

Other observations

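None of the values in this part comes from a test chosen after the result was seen. Rn45s took 84.2 ± 0.31% (SD, n = 3) of the reads in non-diabetic saline, 85.4 ± 1.14% (SD, n = 4) in diabetic saline and 86.1 ± 0.85% (SD, n = 3) in diabetic Esm-1. Over the 12 pairs of replicates, the squared differences in read counts were 1.5 to 4.47 times those of counting alone (chi-square per degree of freedom). So no 2 replicates of a group differed by counting error alone, which does not settle whether they came from separate animals.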
